A study of Mus musculus with 2 samples.

How the data were processed

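Nuclei from gastrocnemius-plantaris (GP) muscle, the calf muscle of the mouse hindlimb, were profiled with a droplet assay that reads RNA and open chromatin from the same nucleus. A first library came from control mice and a second from KIC mice, a model of pancreatic cancer with muscle wasting (cachexia), both at 66 days of age. Per the labels' protocols, the nuclei of 3 muscles were pooled for each library, stained with an antibody against the nuclear pore complex, sorted by FACS for stained nuclei, and loaded at about 5000 nuclei. The pools carry no mark of the animal a nucleus came from, so each group is 1 sample.

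The authors deposited 1 matrix per library of raw counts per feature and nucleus barcode. Gene counts are UMIs (unique molecules) for 32285 genes. Peak counts are transposition events, since 84.3% of the non-zero peak values in control and 88.0% in KIC are even, as fragments with both ends in a peak give. Cell Ranger ARC 2.0.0, Seurat 4.0.4, Signac 1.4.0 and the builds mm10 and GRCm38 are named in the submitters' processing notes, with no role or order. The rules for calling nuclei and peaks, and the aligner settings, are not given in the sources used here. The peak lists of the libraries differ in position and number, so peaks were called for each library by itself.

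The files hold 4398 control and 5640 KIC barcodes, with 24927158 and 31244746 UMIs and 48352987 and 63270085 counts in peaks. A nucleus was kept with at least 200 genes, at most 10% mitochondrial UMIs and at least 500 counts in peaks, which left 3732 control and 5144 KIC nuclei. Doublets were then removed. Because a score from simulated doublets gave no usable threshold, a rule chosen after seeing the data was used in its place. A nucleus was called a doublet when at least 1% of its UMIs came from Ttn, Neb, Trdn and Ryr1 and at least 0.2%, and at least 3 UMIs, came from 64 markers of other cell types that muscle-poor nuclei hold at more than 3 times the level of muscle-rich ones. The rule removed 720 control nuclei (19.3%) and 406 KIC nuclei (7.89%), and it cannot see doublets of 2 myonuclei. It may also miss more doublets in KIC, where these muscle genes were lower. They gave 821605 of 19266998 UMIs in the KIC body myonuclei named below and 630888 of 8646387 in the control ones. The kept sets held 3012 control and 4738 KIC nuclei, with medians of 3210.5 and 4216.5 UMIs and 3653.5 and 6718.5 peak counts.

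Nuclei of both libraries were clustered together without integration, on 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1. Clusters were named from 19 marker lists. A name other than body myonucleus needed at least 3 markers above the other clusters, by at least 1 on the log2 scale. It also needed no larger number of another class's markers among the cluster's 10 leading genes. For the junctional and slow classes the log2 threshold was 2, over other myonuclear clusters only. Myonuclear means a median of at least 1% of UMIs from Ttn, Neb, Trdn and Ryr1. A remaining myonuclear cluster was named body myonucleus with at least 3 body markers at 5 times or more their level in muscle-poor nuclei. A myonuclear cluster led by markers of muscle-poor nuclei was called mixed, and a cluster with a median UMI count more than 3 times below that of its library and no marker among its leading genes stayed unnamed. Body myonuclei, which make up most of a fibre, were divided into type IIb-like and type IIx/IIa-like clusters. Each cluster was set against the other body myonuclei of the library that held most of it, and it took the type whose markers had the higher mean log2 ratio if that mean was above 0.25 and at least 3 markers reached 0.25, with no subtype otherwise. These numeric thresholds were set after the data had been seen. The names are rebuilt from markers, so class sizes can differ from those under other names.

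Counts were summed over the nuclei of a class and given as CPM, counts scaled to the same total in each class and library. The log2 ratio of KIC over control carries a 95% exact conditional binomial (Clopper-Pearson) interval, and shares carry an exact binomial one, except that a share of 0 is given the limit of 3 nuclei over the total. All intervals cover counting error only. With 1 library per group there is no replicate check, no test was run, and no difference can be assigned to the condition rather than to the library. A count of 0 was replaced by a floor of 3 counts over the class, which gives a bound, and no ratio is given where both libraries hold 3 or fewer. Classes with at least 100 nuclei in each library were compared: body myonuclei, fibro-adipogenic progenitors (FAPs, the connective-tissue progenitors of muscle) and myotendinous junction myonuclei.

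Each of 25 gene lists was summarised by the median log2 ratio of its members with at least 20 UMIs over both libraries, and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list outside the percentiles 2.5 to 97.5 is said to stand apart, as a description of these libraries. The named genes follow a fixed rule. In body myonuclei they are the 15 highest and 15 lowest log2 ratios among genes with at least 20 CPM in one library and 50 UMIs, without mitochondrial, sex-linked and unnamed transcripts, that kept their sign in both fibre subtypes. In the other classes they are the 6 highest and 6 lowest with at least 50 CPM that are not higher in body myonuclei. A gene among the 15 lowest is not reported here. A set of 11 genes is always named, with up to 4 members of each list. A gene with 3 or fewer UMIs in both libraries of a subtype has no sign there. That reading of the rule was set after values had been seen, and it took Serpina3m out of the 15 highest and put Depp1 in. The gene lists, markers, comparisons and 18 of the 21 alternatives were fixed before the data were examined.

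Peaks were shared between libraries when they overlapped reciprocally by at least 50%, and their counts were scaled by the counts in shared peaks of body myonuclei. Because both ends of a fragment are counted, intervals for peaks were computed on counts divided by 2, a choice made after peak values had been seen. Coordinates are those of the files on mm10, and whether starts count from 0 or 1 is not recorded. Gene positions came from a RefSeq table of assembly GRCm38.p6 with no strand, matched by symbol for 26259 genes and by synonym for 359. Transcription start sites could therefore not be used, as planned, and each gene was given the one of its ends, within 1 kb, that held the more counts over both libraries.

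The alternatives were a stricter nuclei filter (500 genes, 5% mitochondrial UMIs), doublets kept, resolutions 0.5 and 2, centring each gene within its library, scaling by the trimmed mean of M-values (TMM), the mean of each nucleus's CPM, type IIb-like nuclei only, thinning each nucleus to 1000 UMIs, list members with at least 100 UMIs or at least 1 UMI, a reciprocal overlap of 90%, merged regions, other scalings of peak counts, peaks with at least 200 counts, and 200 UMIs and 200 counts for the gene-end relation. After seeing the data, 3 more were added: body myonuclei without the KIC clusters whose myosin CPM lay below 20% of the median cluster, body myonuclei without the KIC clusters that had no subtype, and the counts of both gene ends summed.

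The calculations were tested on simulated data for the body comparison, with 200 of 13595 genes changed. Counts were drawn as independent Poisson values for each gene, without spread between libraries or genes that vary together. The rates found in the simulation therefore need not hold for the real genes and lists. The interval held 0 for 95.7% of the 13395 unchanged genes once a shift of -0.15, which the changed genes impose on every ratio, was allowed for. Before that allowance, genes simulated at log2 1, -1, 2 and -2 came back with medians of 0.86, -1.14, 1.86 and -2.17. A list of 20 genes simulated at log2 1 reached percentile 100, and 8 of 100 lists of unchanged genes fell outside the percentiles. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.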

Results

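RNA and chromatin accessibility were measured in single nuclei of GP muscle from control and KIC mice to ask how the nuclei of a wasting muscle differ from those of a healthy one. Each group was 1 library of pooled nuclei from 3 mice, with 4398 barcodes and 24927158 UMIs in control and 5640 barcodes and 31244746 UMIs in KIC. After filtering and removal of doublets, 3012 control nuclei with a median of 3210.5 UMIs and 4738 KIC nuclei with a median of 4216.5 UMIs were compared. The doublet rule had removed 19.3% (18.0 to 20.6) of control nuclei and 7.89% (7.17 to 8.66) of KIC nuclei. No replicate check exists for any difference below, and every interval covers counting error only.

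Body myonuclei-like nuclei, which lie along the length of fast fibres, were the most numerous class in both libraries. They made up 1696 of 3012 control nuclei, or 56.3% (54.5 to 58.1), and 3531 of 4738 KIC nuclei, or 74.5% (73.3 to 75.8), and with doublets kept 45.7% and 68.95%. FAP-like nuclei made up 17.0% (15.7 to 18.4) in control and 12.98% (12.0 to 14.0) in KIC. Myotendinous junction-like myonuclei, which lie where fibre and tendon meet, made up 3.52% and 2.11%, and macrophage-like nuclei 2.46% and 2.30%. Slow myonuclei were 1.53% and 0.781%, tenocytes 1.63% and 0.485%, endothelial nuclei 1.16% and 0.633%, and satellite cells, the muscle stem cells, 0.863% and 1.12%. In the endothelial cluster 7 markers of smooth muscle or pericytes were also raised, and Myh11 was among its leading genes, so it may hold such nuclei too. Neuromuscular junction myonuclei were 0.531% and 0.844%, Schwann-like nuclei, whose leading genes included the pigment genes Dct and Tyr, 0.764% and 0.570%, lymphatic endothelial nuclei 0.432% and 0.591%, and adipocytes 0.598% and 0.422%. Small classes also carried muscle RNA, with Ttn, Neb, Trdn and Ryr1 together at 75.3% of the body level in control and 50.7% in KIC satellite cells and at 18.7% and 31.7% in macrophages. These levels are summed over each class, and most of its nuclei held far less. The median share of UMIs from these genes was 0.085% in the satellite cell cluster and 0.041% in the macrophage cluster. It was 7.50% in body cluster 0 and 2.03% in body cluster 1. An unnamed cluster of low depth held 7.64% of control and 0.675% of KIC nuclei, and a mixed cluster 5.54% and 1.96%. The unnamed cluster was myonuclear, with a median of 6.95% of UMIs from Ttn, Neb, Trdn and Ryr1 and Myh4 at 4062 CPM. The body shares leave these nuclei out, which lowers the control share more than the KIC share. The FACS gate, the loss of unequal numbers of doublets and the lower depth of the control library can all set these shares.

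The body myonuclei of the libraries fell largely into different clusters, and with 1 library each such clusters may reflect the library rather than a type. Control nuclei lay in cluster 0 (1005 nuclei, type IIb-like), cluster 8 (361, no subtype) and cluster 5 (295, type IIx/IIa-like). KIC nuclei lay in clusters 1 (976, no subtype), 3 (672, type IIb-like), 4 (651, no subtype), 6 (425, type IIb-like), 7 (381, type IIx/IIa-like), 12 (218, no subtype) and 5 (169). Type IIb-like nuclei were 60.9% (58.5 to 63.2) of control and 31.9% (30.4 to 33.5) of KIC body myonuclei, type IIx/IIa-like nuclei 17.7% and 15.6%, and nuclei of no subtype 21.4% and 52.5%. The myosin genes that define the subtypes also differed between the libraries, so these sizes describe the clusters and not fibre numbers. All body values below are summed over these clusters, 8646387 UMIs in control and 19266998 in KIC.

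Body myonuclei of the KIC library held far more RNA of denervation-type and atrophy genes and less RNA of the contractile and calcium-release machinery than those of the control library. Fbxo32 and Trim63, which encode the muscle ubiquitin ligases atrogin-1 and MuRF1, stood at 5659 and 5736 CPM in KIC against 1477 and 1755 CPM in control, log2 ratios of 1.94 (1.91 to 1.96) and 1.71 (1.68 to 1.73). Ankrd1, an ankyrin-repeat protein of stressed muscle, had 3375 UMIs in KIC and 0 in control, at least 505-fold higher over a floor of 3 UMIs. Runx1, a transcription factor of denervated muscle, was higher by a log2 ratio of 6.60 (6.18 to 7.05), and Ncam1, an adhesion molecule that spreads along denervated fibres, by 6.39 (6.00 to 6.81). Myog, the muscle regulator myogenin, stood at 26.3 CPM against 2.89 CPM, a log2 ratio of 3.18 (2.6 to 3.82), and Chrna1, the alpha subunit of the acetylcholine receptor, had a ratio of 4.51 (3.37 to 5.97). Fst, which encodes the activin and myostatin antagonist follistatin, had 813 UMIs against 3 and a ratio of 6.93 (5.37 to 9.21). Mstn, myostatin itself, was lower in KIC, 15.5 against 37.0 CPM (-1.26, -1.49 to -1.03), although its ratio was 0.48 within the type IIx/IIa-like nuclei. Myh4, the myosin of type IIb fibres, stood at 1617 CPM in KIC and 3798 CPM in control (-1.23), Myh2 at 262 and 520 CPM (-0.99) and Myh1 at 666 and 788 CPM (-0.24). The direction of Myh1 turned without the low-myosin KIC clusters (0.19) and without those of no subtype (0.64), and that of Myh1 and Myh2 turned in type IIb-like nuclei. Without the KIC clusters of no subtype the ratios were 4.61 for Ncam1, 4.59 for Runx1, 4.72 for Fst, 3.31 for Chrna1, 1.00 for Myog, -0.58 for Mstn, -0.75 for Myh4 and -0.02 for Myh2, and in type IIb-like nuclei they were 4.99 for Runx1, 0.82 for Myog, 0.93 for Trim63 and 1.39 for Fbxo32.

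The other genes with the 15 highest ratios were Kcnk5, a potassium channel (8.22, 7.0 to 9.85), Enpp3 (7.86), Frmd5 (7.77), Sh3rf1 (7.01), Sln, which encodes the calcium-pump inhibitor sarcolipin (6.92, 6.22 to 7.73), Serinc5 (6.65), Pakap, a symbol that occurs more than once in the files (6.61), Id3, an inhibitor of helix-loop-helix factors with 2 control UMIs (6.45, 4.58 to 9.50), Hhipl1 (6.44), Sh3d19 (6.33) and Depp1 with 3 control UMIs (6.26, 4.71 to 8.54). Among the 15 lowest was Rasgrp2, an exchange factor of Ras-family proteins, at 0.47 CPM in KIC and 21.6 CPM in control (-5.53, -6.68 to -4.58). The others named here are Pebp4 (-3.90), Map2k6, a kinase upstream of stress-activated MAP kinases (-3.85), Col24a1 (-3.75), Fat3 (-3.62), Gdap1 (-3.51), Adamtsl1 (-3.51), Grb14, an adaptor that binds the insulin receptor (-3.49), and Htra1 (-3.44), with Itga4 (-3.38), Igfbp5, a binding protein of insulin-like growth factors (-3.25), Pde4a, a cyclic AMP phosphodiesterase (-3.15), Ces1d (-3.09) and Sparcl1 (-3.06). The same direction in both fibre subtypes was a condition for naming these genes. Pebp4, Gdap1 and Map2k6 are also leading genes of control cluster 0, Depp1 of KIC cluster 1, Enpp3 of cluster 12, and Hhipl1, Frmd5, Runx1 and Sh3rf1 of cluster 4, so their ratios and the clusters are not independent.

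**Figure D1:**
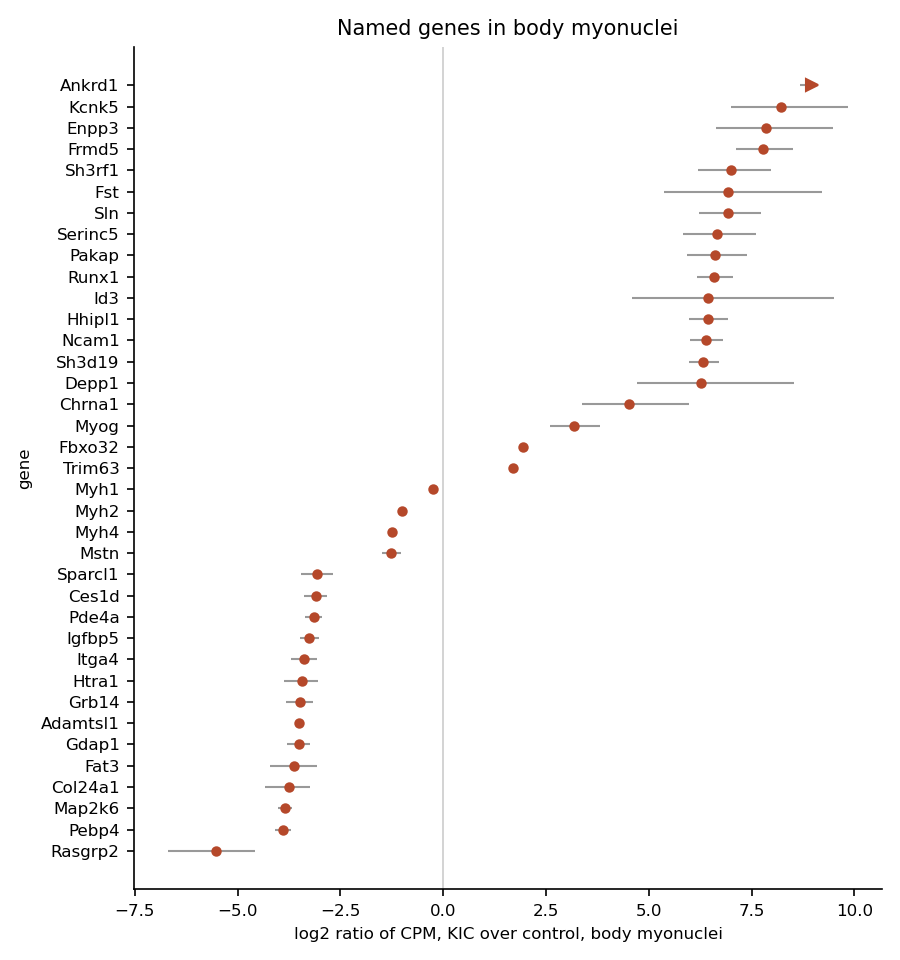
Log2 ratio of CPM, KIC over control, of the genes named by rule and of the always-named genes in body myonuclei, 1 library per group. Points are ratios, lines their 95% counting intervals, and the triangle marks the lower bound for Ankrd1, which had 0 UMIs in control.

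Lists of protein breakdown stood apart on the higher side in body myonuclei. Scaling by TMM places the centre of the genes at a log2 ratio of 0.23 in this class, and members are counted as higher below only where they exceeded that shift, while medians and ratios are given before that scaling. The denervation response list had a median of 3.86 (percentile 100) and 14 of 16 measured members higher, among them Kcnn3, a calcium-activated potassium channel (5.63). The list of atrophy ubiquitin ligases had a median of 0.79 (percentile 99.99) and 13 of 19 members higher, with Eda2r, a receptor of the tumour necrosis factor family, at 3.63 and the ubiquitin gene Ubb at 2.31. All 32 proteasome subunits were higher, with a median of 1.02 (percentile 100), from Psmd8 at 1.66 and Psmd13 at 1.55 downwards. Autophagy genes had a median of 0.65 (percentile 99.8) with 17 of 24 higher, including the lysosomal proteases Ctsl at 4.07 and Ctsb at 1.70 and the autophagosome proteins Gabarapl1 at 2.41 and Map1lc3b at 1.73.

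Lists of hormone, cytokine and stress signals stood apart on the same side. The IL-6, STAT3 and acute-phase list had a median of 1.84 (percentile 100) and 13 of 15 members higher. Its member Serpina3n had 436 UMIs in KIC and 0 in control, at least 65.2-fold higher, and the oncostatin M receptor gene Osmr stood at 3.96, Junb at 3.72 and Socs3, a feedback inhibitor of cytokine signalling with 1 control UMI, at 4.68 (2.14 to 10.01). The glucocorticoid target list had a median of 0.60 (percentile 99.89) and 11 of 18 higher, led by the metallothioneins Mt2 at 2.69 and Mt1 at 2.47 and by Errfi1 at 2.19 and Pik3r1 at 1.44. Of its 19 members, 9 also belong to other lists. The insulin, IGF and mTOR list had a median of 0.84 (percentile 100) and 18 of 24 higher, with Akt1 at 3.18, Eif4ebp1, a translation repressor, at 2.43 and Igf1 at 2.08, but with Igfbp5 among the lowest genes. It no longer stood apart without the KIC clusters of no subtype (0.31, percentile 97.2). All 13 measured genes of the unfolded-protein and oxidative stress list were higher (median 0.99, percentile 99.83), such as Hspb1 at 2.75, Gclm at 1.92 and Atf4 at 1.64. The immediate-early list had a median of 1.81 (percentile 100) with 12 of 16 higher, for example Egr1 at 4.25, Atf3 at 3.06 and Ier2 at 2.67, although the summed level of the 16 genes was only 302 CPM in control and 349 CPM in KIC. The clock list had a median of 0.55 at percentile 97.75, with 13 of 18 higher, including Nr1d1 at 2.73, Cry2 at 2.72 and Dbp at 2.08. It no longer stood apart in 7 alternatives, with a lowest percentile of 90.1.

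**Figure D2:**
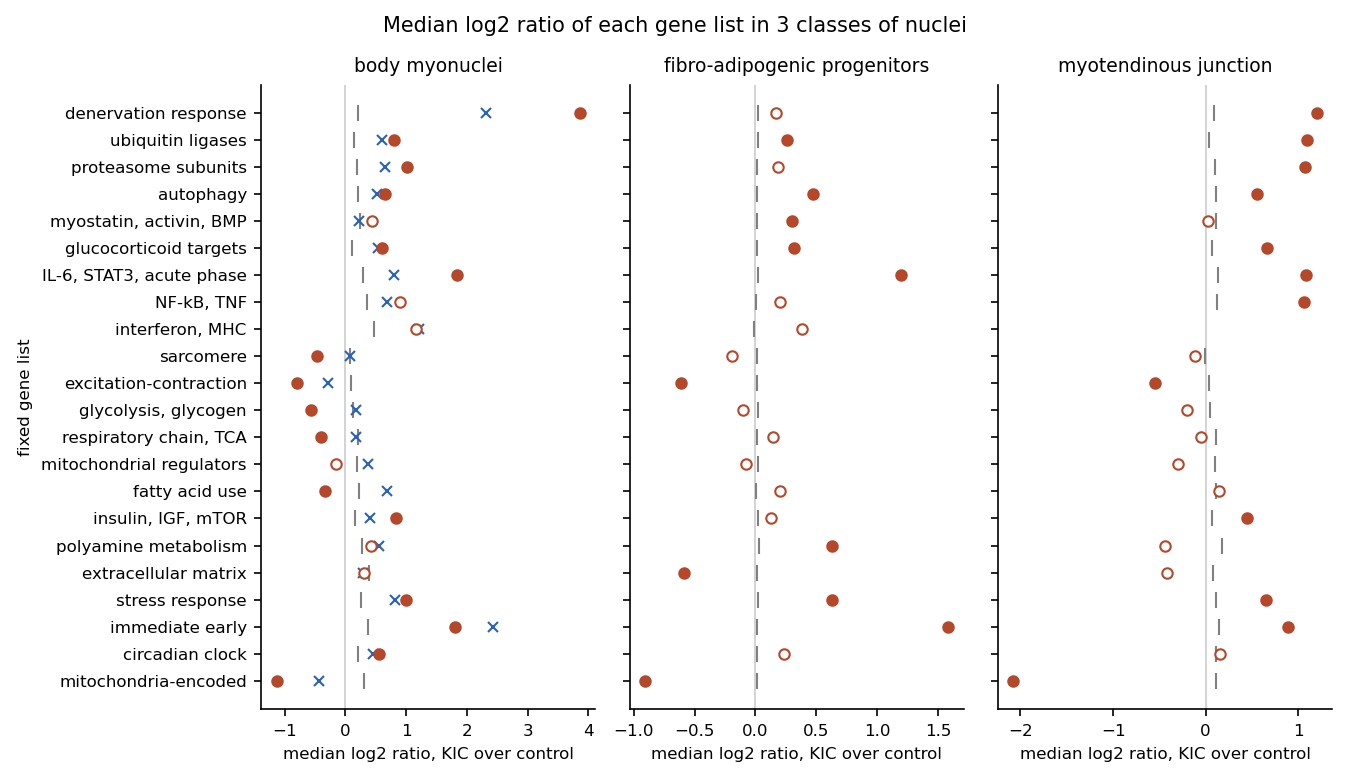
Median log2 ratio, KIC over control, of each gene list in body myonuclei, FAP and myotendinous junction nuclei, 1 library per group. Filled points stand apart from 10000 matched random lists, open points do not, and grey ticks mark the median of the random lists. Blue crosses give type IIb-like nuclei alone, where sarcomere, glycolysis, oxidative and fatty acid lists lie above 0. Of these, only the fatty acid list exceeds the TMM shift of 0.20 in type IIb-like nuclei.

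Contractile and metabolic lists stood apart on the lower side. The list of excitation-contraction coupling had a median of -0.79 (percentile 0), with 17 of 20 members below the shift, including the calcium buffer Pvalb at -1.52, the junctophilin Jph1 at -1.42, the calcium-release channel Ryr1 at -1.32 and the chloride channel Clcn1 at -1.31. Sarcomere genes had a median of -0.46 (percentile 0) and 9 of 35 higher. Mybpc2, the fast myosin-binding protein, stood at -2.83 and Myoz1 at -1.71, while Myom3 (2.92) and Lmod2 (2.40) went the other way. Glycolysis and glycogen genes had a median of -0.56 (percentile 0), with the glycogen phosphorylase Pygm at -1.62 and the phosphorylase kinase subunits Phka1 at -1.60 and Phkg1 at -1.56, against Pfkfb3 at 1.70, and 4 of 23 higher. Nuclear genes of oxidative phosphorylation and the TCA cycle had a median of -0.40 (percentile 0) and 2 of 33 higher, with Sdhc at -0.85, Cycs at -0.84 and Cox6a2 at 1.19. Fatty acid use had a median of -0.33 (percentile 0.01) and 4 of 23 higher, with Plin5 at -2.20, Ucp3 at -1.48, Plin2 at 2.18 and Acot2 at 2.5. Mitochondrially encoded RNA, a sign of cytoplasmic carry-over and RNA quality, was lower for all 12 measured genes (median -1.13, percentile 0), and it was lower in KIC in each of the other classes compared.

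These lower lists depended on which nuclei were set side by side. The choice fixes this in part. Subtypes were called on markers that include Myh4, Mybpc2 and Actn3 of the sarcomere list and Pvalb of the excitation-contraction list. KIC clusters 1 and 12, of no subtype, hold little myosin RNA, so leaving them out raises the KIC myosin levels. Among type IIb-like nuclei alone the medians were 0.07 for sarcomere, 0.17 for glycolysis, 0.18 for oxidative and 0.69 for fatty acid genes. The fatty acid median was at percentile 99.91. The TMM shift in type IIb-like nuclei was 0.20, so the sarcomere, glycolysis and oxidative medians, though above 0, lay below that shift. Myh1 and Myh2 had log2 ratios of 5.08 and 5.91, since KIC cluster 6 is counted there and holds 1605 CPM of Myh1. The excitation-contraction list stayed lower there, at -0.28 (percentile 0.52), as did mitochondrially encoded RNA at -0.43, and the denervation, ubiquitin ligase, proteasome, autophagy and IL-6 lists stayed apart and higher. Medians there were smaller, at 2.32 for denervation, 0.66 for the proteasome, 0.81 for the IL-6 list and 0.41 for insulin, IGF and mTOR, and without the KIC clusters of no subtype denervation stood at 2.16 and the IL-6 list at 1.18. Without those clusters sarcomere (0.01, percentile 44.7), glycolysis (-0.01, 25.7) and fatty acid genes (0.000311, 14.5) no longer stood apart, and oxidative genes stood at -0.07 (1.6). The larger type IIb-like KIC clusters also differed in denervation genes. Cluster 6 held 383 CPM of Ncam1 and 314 CPM of Runx1, against 4.32 and 6.98 CPM in cluster 3. Denervation values of type IIb-like nuclei therefore do not describe each of these clusters.

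The remaining lists did not stand apart in body myonuclei. The myostatin, activin and BMP list had a median of 0.45 (percentile 88.5) and 12 of 20 higher, with Id2 at 5.99 on 2 control UMIs (4.12 to 9.04) and Id1 at 4.87. The NF-kB and TNF list had a median of 0.89 (percentile 96.1, 6 of 9 higher, Tnfrsf12a, the TWEAK receptor, at 2.53) and stood apart in 3 alternatives, with a highest percentile of 98.01. Interferon and antigen-presentation genes had a median of 1.17 (percentile 93.2, 5 of 6 higher, H2-K1 at 2.04) and stood apart when genes were centred within each library (1.54, 98.1) and for members with at least 1 UMI (1.43, 99.45). Mitochondrial regulators had a median of -0.15 (percentile 3.54, 4 of 15 higher) that turned to 0.38 (93.2) in type IIb-like nuclei, with the nuclear receptors Ppara at -2.27 and Esrrg at -1.91 lower overall and 1.72 and 1.33 in type IIb-like nuclei. Polyamine genes were divided, 5 of 10 on each side (median 0.42, percentile 73.6), with the oxidase Paox at 4.11 and ornithine decarboxylase Odc1 at 1.94 against spermine oxidase Smox at -2.06. Their list stood apart for members with at least 100 UMIs (1.00, percentile 99.7) and after thinning (0.89, 98.5). Extracellular matrix genes had a median of 0.30 (percentile 35.4) and 10 of 20 higher, including Lox at 5.94 on 1 control UMI, Tgfb1 at 5.77 on 2, Mmp2 at 3.60 and Sparc at 3.09. That median was -0.24 (percentile 0.58) when nuclei were weighted equally and 1.74 (percentile 99.98) for members with at least 100 UMIs. Over all kept nuclei, the sex-linked list stood at 1652 CPM in control and 2115 CPM in KIC, almost all of it Xist, the erythroid list at 7.63 and 10.4 CPM and the pancreas and tumour list at 0.654 and 0.743 CPM.

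The KIC clusters carried the denervation-type and the atrophy genes to different extents. Fbxo32 stood at 13064 CPM and Trim63 at 15073 CPM in cluster 1, against 3452 and 2857 CPM in cluster 4 and 1642 and 2027 CPM in control cluster 0. Ncam1 stood at 1128 CPM in cluster 4 and 1506 CPM in cluster 12, against 3.54 CPM in cluster 1, 4.32 CPM in cluster 3 and 2.08 CPM in control cluster 0. Between these, it stood at 383 CPM in KIC cluster 6, which is type IIb-like as cluster 3 is. Myog was also highest in clusters 4 and 12, at 61.3 and 77.6 CPM, with 1.77 CPM in cluster 1 and 4.37 CPM in control cluster 0, and so was Fst, at 87.8 and 164 CPM, with 0.590 and 0.208 CPM there. Myh4 was at 21.2 CPM in cluster 1, 278 CPM in cluster 12, 157 CPM in the type IIx/IIa-like KIC cluster 5 and 726 CPM in cluster 7, against 1789 to 4048 CPM in clusters 3, 4 and 6. Clusters were formed on the same counts, and Runx1 and Gadd45a are leading genes of cluster 4 and Cry2 of cluster 1, so these values describe the clusters.

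**Figure D3:**
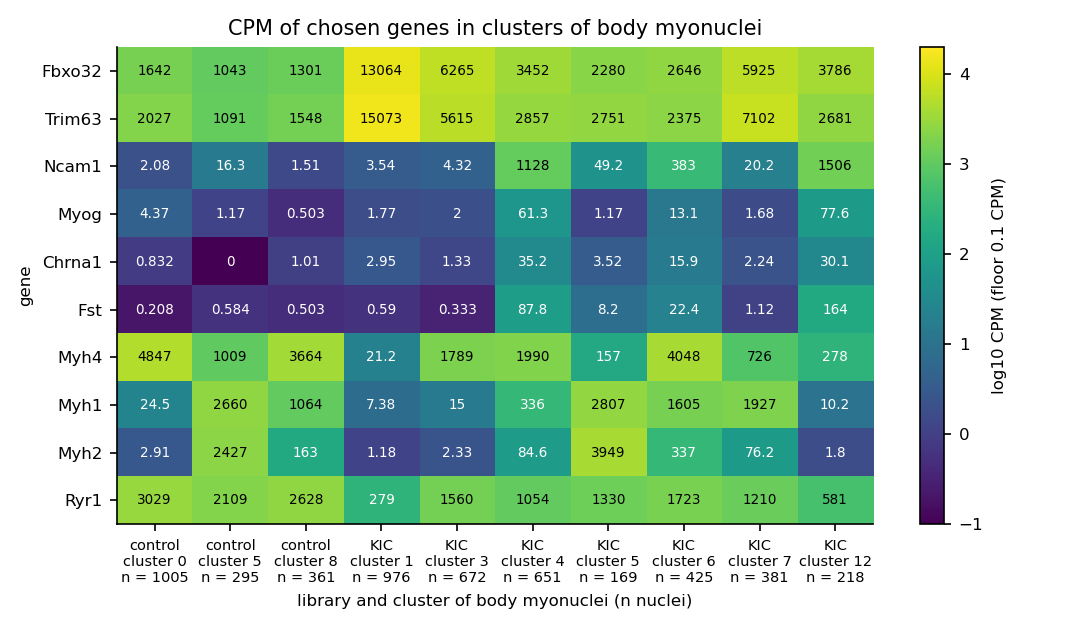
Log10 CPM (colour) of chosen genes (vertical axis) in each body myonuclear cluster and library with at least 100 nuclei (horizontal axis), with CPM printed in the cells. KIC cluster 1 holds the most Fbxo32 and Trim63, and KIC clusters 4 and 12 the most Ncam1, Myog and Fst.

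At least 1 Myog UMI was seen in 22 of 1696 control body myonuclei, 1.30% (0.815 to 1.96), and in 303 of 3531 KIC body myonuclei, 8.58% (7.68 to 9.55), at median depths of 4205 and 4627 UMIs. With every nucleus thinned to 1000 UMIs, which left out 75 control and 23 KIC nuclei, the shares were 0.247% (0.0673 to 0.631) and 1.82% (1.41 to 2.32). Among type IIb-like nuclei alone the KIC share was 3.10%, since Myog RNA lay mainly in KIC clusters 4 and 12. Endothelial nuclei, which should lack the gene, showed 0 of 35 in control and 0 of 30 in KIC at median depths of 1707 and 2276 UMIs, which by the share of 3 nuclei allows up to 8.57% and 10%. Thinned, they showed 0 of 30 and 0 of 29 with 5 and 1 nuclei left out. FAP nuclei gave 0 of 513 in control, which allows up to 0.585%, and 1 of 615 in KIC, 0.163% (0.00412 to 0.903), at median depths of 2089 and 1975 UMIs. Thinned, they gave 0 of 390 and 1 of 506, with 123 and 109 left out. The KIC body share lay above the FAP share in both forms, and the endothelial nuclei were too few to set a lower background.

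FAP nuclei of the KIC library held more RNA of cytokine-response and acute-phase genes and less RNA of extracellular matrix genes than those of the control library. They came from clusters 2 (274 control and 454 KIC nuclei), 9 (180 and 115) and 15 (59 and 46), with 1345156 and 1538065 UMIs and a TMM shift of 0.02, above which members are counted as higher. The chemokine gene Cxcl13 had 146 UMIs in KIC and 0 in control, at least 42.6-fold higher, and Igfbp3, a binding protein of insulin-like growth factors, stood at 614 CPM against 24.5 CPM (4.65, 4.15 to 5.19). Complement component C4b (4.44), Junb (4.13), the acute-phase gene Serpina3n (3.46) and the aldehyde oxidase Aox3 (2.96) followed. The lowest were Adamtsl2, with 3 KIC UMIs (-5.08, -7.39 to -3.49), Ano4 (-3.36), Nrep (-2.71), the collagen Col15a1 (-2.5), which is also a marker of the class, Col5a3 (-2.37) and the phosphodiesterase Pde8b (-2.30). Igfbp3 is a leading gene of cluster 2 and Col15a1 of cluster 9, so the differing mix of clusters enters their ratios.

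The IL-6, STAT3 and acute-phase list had a median of 1.20 in FAPs (percentile 100, 13 of 14 measured members higher), including Osmr at 1.80 and Pim1 at 1.63. The immediate-early list had 1.58 (percentile 100, 12 of 13 higher; it shares Junb with the former), with Zfp36 at 2.00 and Egr1 at 1.71. Autophagy had 0.47 (percentile 100, 19 of 23, Ctsl at 1.69 and Map1lc3b at 1.36) and glucocorticoid targets 0.32 (percentile 99.8, 13 of 18, Mt2 at 2.82 and Mt1 at 2.56). The stress list had 0.63 (percentile 99.7, 7 of 7, Txnrd1 at 1.15), polyamine genes 0.63 (percentile 99.1, 6 of 7, Azin1 at 0.72), the myostatin, activin and BMP list 0.30 (percentile 99.0, 14 of 17, the activin receptor Acvr1b at 1.75 and Id3 at 1.55) and ubiquitin ligases 0.26 (percentile 98.5, 14 of 18, Ubb at 1.42). Extracellular matrix genes had a median of -0.59 (percentile 0) with 19 of 27 lower, among them Col6a2 at -1.51 and Col3a1, at 543 CPM against 1314 CPM, at -1.28, while the collagen cross-linking enzyme Lox stood at 2.84. With members of at least 100 UMIs, the autophagy (0.23), myostatin (0.24), ubiquitin ligase (0.23) and stress (0.41) lists no longer stood apart, nor did the stress (0.45) and polyamine (0.42) lists at resolution 0.5 and the polyamine list (0.61) with nuclei weighted equally. All 12 mitochondrially encoded genes were lower (median -0.91, percentile 0), and so were the 9 measured excitation-contraction genes (-0.61, percentile 0.095), such as Ryr1 at -1.35.

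The other lists lay within the percentiles in FAPs. Medians were 0.17 for denervation (percentile 77.1), 0.19 for the proteasome (94.9), which stood apart with doublets kept (0.32, 99.6), 0.20 for NF-kB and TNF (87.2), 0.38 for interferon (93.8), 0.24 for the clock (97.0), 0.13 for insulin, IGF and mTOR (89.6) and 0.20 for fatty acid use (90.8). They were 0.15 for oxidative genes (86.1), -0.07 for mitochondrial regulators (24.4), -0.11 for glycolysis (16.2) and -0.19 for sarcomere genes (6.25). Medians of the oxidative, regulator and glycolysis lists changed sign in some alternatives (to -0.05 for oxidative genes and 0.03 for regulators with members of at least 100 UMIs, and to 0.07 for glycolysis when genes were centred). The sarcomere list stood apart in 5 alternatives, on the higher side (0.30) when genes were centred within each library and on the lower side in 4. Of the always-named genes, Fbxo32 stood at 345 CPM against 87.0 CPM (1.99, 1.70 to 2.29), Trim63 at 332 CPM against 81.8 CPM (2.02, 1.72 to 2.33) and Runx1 at 1.68, while Ncam1 stood at -1.19, Myh4 at -1.90 and Myh2, with 3 KIC UMIs, at -3.13 (-5.51 to -1.41). Fst was at 87.7 CPM in control and 90.4 CPM in KIC and Myh1 at 5.2 CPM in each library, and Myog, Mstn and Chrna1 had at most 1 UMI. Muscle RNA reaches this class: Ttn, Neb, Trdn and Ryr1 together stood at 1.53% of the body level in control and 1.74% in KIC, and Fbxo32 and Trim63 together at 5.22% and 5.94%.

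Myotendinous junction nuclei of the KIC library also held more ubiquitin ligase and proteasome RNA, on 106 control and 100 KIC nuclei of cluster 13 with 663684 and 537952 UMIs. Fbxo32 stood at 4508 CPM against 838 CPM (2.43, 2.29 to 2.56) and Trim63 at 5361 CPM against 1163 CPM (2.20, 2.09 to 2.32). The highest ratios belonged to the stress-induced factor Atf3, with 3 control UMIs (5.85, 4.27 to 8.14), Ankrd1 (4.35, 3.69 to 5.11), the small heat-shock proteins Hspb1 (4.26) and Hspb7 (2.69), Nrxn3 (3.99) and Xirp1 (2.6). The lowest belonged to Kitl (-5.91, -11.23 to -3.38) and Rp1 (-5.45, -10.78 to -2.91) with 1 KIC UMI each, Ces1d (-4.02), Nebl (-3.94) and the slow myosin Myh7 (-3.94) with 3 each, and Cald1 (-3.74). Runx1 was at 2.27, Ncam1 at 0.69, Fst at 0.61 (-0.19 to 1.43), Myh4 at -1.38, Myh1 at 1.10, Myh2 at 0.51, Mstn at -1.16 (-3.26 to 0.60) and Myog, on 1 and 4 UMIs, at 2.30 (-1.03 to 7.92). The TMM shift of this class was 0.11, and members below are counted as higher above it.

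On the higher side stood denervation (median 1.20, percentile 100, 9 of 10 higher), ubiquitin ligases (1.09, percentile 100, 16 of 18, Ube4a at 1.59) and the proteasome (1.07, percentile 100, 24 of 26, Psma5 at 2.30). Glucocorticoid targets (0.66, percentile 99.97, 13 of 18), the IL-6 list (1.09, percentile 99.94, 6 of 7, the receptor gene Il6ra at 2.01), autophagy (0.56, percentile 99.3, 16 of 22, Ctsl at 3.56), insulin, IGF and mTOR (0.44, percentile 99.2, 16 of 20) and stress genes (0.65, percentile 97.8, 7 of 9) also did. So did the immediate-early list (0.89, percentile 98.5) with 5 members measured and the NF-kB list (1.06, percentile 98.1) with 4, and these medians were -0.17 for members with at least 100 UMIs and -0.02 for members with at least 1 UMI. Each of these 2 lists no longer stood apart in 2 further alternatives, and the stress list in 7. The same held for insulin, IGF and mTOR (0.21) and the IL-6 list (0.74) with nuclei weighted equally, for the IL-6 list (percentile 97.3) and autophagy (0.45) with members of at least 100 UMIs, and for insulin, IGF and mTOR with doublets kept (0.35). Excitation-contraction genes (-0.55, percentile 0.02, 4 of 19 higher, Srl at -1.29 and Ryr1 at -1.02) and the 7 measured mitochondrially encoded genes (-2.08, percentile 0) stood apart on the lower side. Within the percentiles lay sarcomere (-0.12, 20.2), glycolysis (-0.20, 6.61), oxidative genes (-0.05, 16.1), mitochondrial regulators (-0.30, 3.77), fatty acid use (0.14, 56.7), polyamines (-0.43, 4.92; 0.49 for members with at least 100 UMIs), extracellular matrix (-0.42, 4.33), the clock (0.15, 58.0) and the myostatin list, whose median of 0.02 (33.5) was -0.09 after TMM scaling. On the lower side, glycolysis stood apart with nuclei weighted equally (-0.53) and with the stricter filter (-0.30), extracellular matrix genes with nuclei weighted equally (-0.64), and mitochondrial regulators for members with at least 100 UMIs (-0.48) and at resolution 0.5 (-0.34). No interferon gene reached 20 UMIs there.

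Open chromatin was compared through peaks called in each library. Control had 83521 peaks covering 74.2 Mb and KIC 89350 covering 81.6 Mb, with 652 and 775.5 counts per kb. Of the control peaks 80.2% (79.9 to 80.4) overlapped a KIC peak by at least 1 bp, and of the KIC peaks 75% (74.7 to 75.3) overlapped a control peak. Peaks without a partner were weaker, with medians of 154 counts against 367 in control and 207 against 440 in KIC. Among peaks with at least 200 counts the overlap was 92.4% and 82.6%, so the gap between the libraries did not narrow. The 66284 shared peaks held 93.4% and 90.01% of the counts.

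In body myonuclei the peaks with the highest ratios lay away from gene ends, inside genes or between them. On chromosome 13, a control peak at 32418647 to 32419449 (KIC 32418489 to 32419751), outside genes with Gmds nearest, had 1048 counts in KIC and 5 in control, a log2 ratio of 6.29 (4.61 to 8.89). A peak on chromosome 2 at 161331594 to 161332429, outside genes with Ptprt nearest, had 268 and 2 counts (5.65, 3.14 to 10.96). Peaks inside Foxred2 on chromosome 15 (5.11, 3.93 to 6.64), inside the kinase gene Tec on chromosome 5 (4.96), inside the zinc transporter gene Slc39a14 on chromosome 14 (4.91) and inside S100a3 on chromosome 3 (4.84, 3 control counts) followed, with regions nearest Gm29946 on chromosome 19 (4.90, 2.38 to 10.22) and Gm41206 on chromosome 14 (4.82, 2.30 to 10.14) on 2 control counts each. The lowest were a region nearest Gm3898 on chromosome 9 (-3.29, -4.22 to -2.45), peaks inside Stau2 (-3.16), Evc (-2.97) and Aff3 (-2.96), a region nearest Igtp (-2.90), a peak inside the calpain gene Capn2 (-2.85), a region nearest Gm11210 (-2.81) and a peak inside Iqgap2 (-2.77).

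At the gene ends of most named genes the differences were smaller than in RNA. For Myh1 this could not be told, since the gene-end interval held both 0 and the RNA ratio of -0.24. Chrna1 had peaks with log2 ratios of 1.00 (0.41 to 1.63) and 2.40 (1.76 to 3.10), and Ncam1 one of 1.55 (0.97 to 2.18). Trim63 stood at 0.44 (0.25 to 0.63) and Fbxo32 at 0.27 (0.11 to 0.42), Myh4 at -0.69 (-0.90 to -0.49) and Mstn at -0.71 (-1.14 to -0.27). For Myog (0.09, -0.12 to 0.32), Fst (0.25, -0.25 to 0.77), Runx1 (0.79, -0.28 to 2.01, on 18 and 83 counts), Myh1 (-0.34, -0.77 to 0.11) and Myh2 (-0.18, -0.88 to 0.56) no difference was detectable at this depth. The peaks of Fst, Runx1 and Myh2 lay at the end coordinate and those of Myog and Myh1 at the start, and which is the transcription start was not known. In type IIb-like nuclei alone the ratios were 2.38 for Myh1, -0.13 for Myog, -0.31 for Runx1, -0.12 for Fst and 0.01 for Myh2. Across 9868 genes with at least 50 UMIs and 50 gene-end counts, the RNA and gene-end ratios had a Spearman rho of 0.328 and the same sign in 61.3%; genes are not independent replicates, and in type IIb-like nuclei alone rho was 0.196. The interquartile range was 0.894 for RNA and 0.277 for gene ends.

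**Figure D4:**
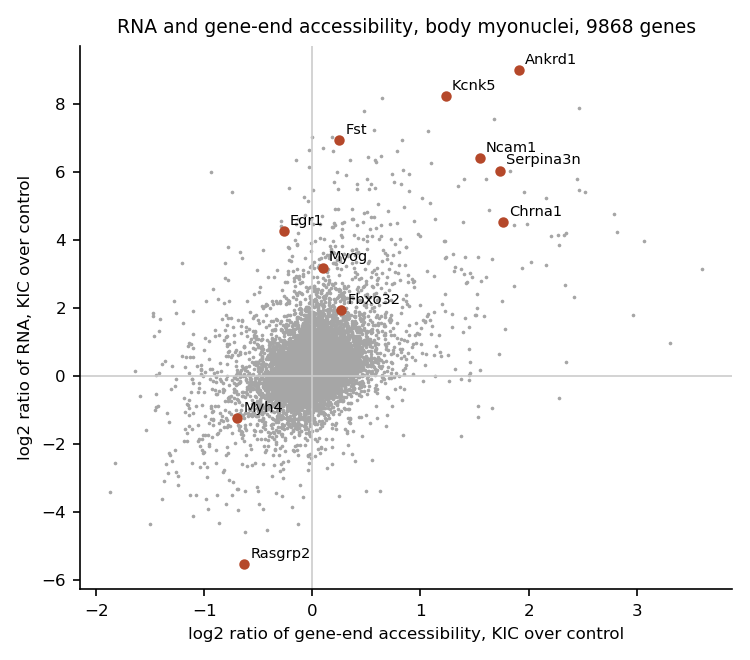
Log2 ratio of RNA (vertical axis) against that of accessibility at the gene end (horizontal axis), KIC over control, in body myonuclei, 1 point per gene for 9868 genes, with named genes labelled. RNA ratios spread more widely than gene-end ratios, and Spearman rho across genes was 0.328.

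Some of the lists that stood apart in RNA also did so at gene ends. The medians were 0.26 for denervation (percentile 99.9, 10 of 13 higher), 0.26 for the IL-6 list (99.99, 9 of 16), 0.14 for the proteasome (99.9, 28 of 31), 0.14 for insulin, IGF and mTOR (99.8), 0.10 for ubiquitin ligases (98.3) and 0.09 for autophagy (98.0), with excitation-contraction genes (-0.15, percentile 0.01) and glycolysis (-0.13, 0.12) on the lower side. Polyamine genes (0.16, 98.9) and the 5 measured pancreas and tumour genes (-1.05, 0.125) stood apart at gene ends without doing so in RNA, where no pancreas gene was measured. Fatty acid use, lower in RNA, lay at 0.04 (81.9). Immediate-early genes (-0.03, 22.4), glucocorticoid targets (-0.03, 26.8), the clock (0.01, 52.8), stress genes (0.04, 78.7), extracellular matrix genes (-0.27, 4.77), sarcomere (-0.05, 8.12) and oxidative genes (-0.03, 14.4) did not.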

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

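The test of depth for the low-myosin nuclei was chosen after the result had been seen, and body and FAP values of immediate-early genes had been seen before their test by class was written. Several genes had ratios of KIC over control that went opposite ways in different classes. These differences between classes were not tested, since each group is 1 library. Ncam1 stood at 6.39 (6.00 to 6.81) in body myonuclei and -1.19 (-1.53 to -0.85) in FAPs. The collagen gene Col5a3 stood at 2.48 (2.13 to 2.85) in body myonuclei, on 71 and 880 UMIs, and -2.37 (-2.66 to -2.09) in FAPs. Cald1, an actin-binding protein, stood at 1.54 (0.66 to 2.56) in body myonuclei, on 12 and 78 UMIs, and -3.74 (-5.08 to -2.65) in myotendinous junction nuclei.

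KIC clusters 1 and 12, together 1194 body myonuclei, held little myosin RNA, with summed Myh1, Myh2 and Myh4 at 115 CPM against 3409 CPM in the other KIC body myonuclei, or 3.39% (3.12 to 3.67). Low depth is argued against, since their median of 3694 UMIs was 71.2% of the 5191 UMIs of the others and CPM does not scale with depth. Loss of RNA from damaged nuclei was set against chromatin, which RNA loss would leave in place. Accessibility at the Myh4 gene end was 23.7% (17.1 to 32.3) of that in type IIb-like KIC nuclei, while it was 127% (112 to 145) at Fbxo32 and 149% (128 to 174) at Trim63. These values cannot decide the question, since the type IIb-like nuclei were named in part by Myh4. The low-myosin nuclei have no subtype, so another fibre type could give the same value, and the Myh1 and Myh2 gene ends were not compared. FAP markers stood at 0.528% (0.475 to 0.586) of their level in FAPs, but this says little on FAP nuclei counted as myonuclei. The doublet rule had used the same markers, and a body cluster needed a median of at least 1% of UMIs from Ttn, Neb, Trdn and Ryr1. Loss of RNA stays open. Wasting in KIC muscle and an effect of the KIC library also stay open, and neither was tested.

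Fbxo32 and Trim63 were higher in KIC FAP nuclei, as they were in myonuclei. Doublets with myonuclei that escaped removal go with part of the level: the 326 of 615 KIC FAP nuclei without a UMI of Ttn, Neb, Trdn or Ryr1 held 26.3% (21.7 to 31.4) of the class's Fbxo32 and Trim63 CPM, and leaving out nuclei with muscle UMIs also removes nuclei with free muscle RNA. Within such nuclei KIC was still 4.27-fold (2.67 to 7.16) higher, 178 against 41.6 CPM. Free RNA from myonuclei cannot be told apart from expression in FAPs: the FAP level was 0.171 (0.159 to 0.184) of that in macrophage nuclei, but macrophage nuclei held muscle genes at 31.7% of the body level and are no clean measure of free RNA. Expression in FAPs of KIC muscle stays open and untested.

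The list medians of immediate-early genes were higher in KIC body myonuclei and FAPs, and such genes can also respond to handling of tissue. Their summed CPM was higher in KIC in 10 of the 11 classes with at least 50 of their UMIs, and its log2 ratio was -0.08 (-0.82 to 0.71) in lymphatic endothelial nuclei. The interval also held 0 in satellite cells (0.28, -0.35 to 0.91) and slow myonuclei (0.17, -0.29 to 0.63). In body myonuclei the summed ratio of 0.21 (0.14 to 0.27) did not exceed the TMM shift of 0.23. Handling cannot be told apart from a response of the animal, because each group was handled as 1 library. Accessibility at the gene ends of this list did not stand apart (-0.03, percentile 22.4).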

How the results depend on the processing

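The 2 exclusions of KIC clusters and the sum of both gene ends were chosen after the data had been seen. No paired analysis was possible because each group is 1 library and no test was run. Of 1759 values from 21 alternatives for 213 results, 1492 gave the same verdict or stayed within the counting interval, 200 moved out of it, 32 no longer stood apart, 21 newly did, and 14 that had stood apart or had an interval without 0 reversed. Of the values not reversed in that sense, 28 changed sign, in lists that did not stand apart or genes and peaks whose interval held 0. Body named genes kept their direction in 36 to 38 of 38 cases, which the naming rule fixes in part for type IIb-like nuclei, but 33 moved in size without the KIC clusters that have no subtype, 25 in type IIb-like nuclei and 24 on thinning, and 12 to 18 body lists stood apart. The cause was not tested unless named. With type IIb-like nuclei only, Myh1 had a log2 ratio of 5.08 and Myh2 of 5.91 in body myonuclei. The sarcomere median was 0.0684 there, glycolysis 0.17, oxidative genes 0.18 and fatty acid use 0.69. These 4 lists are counted as reversed against 0, and only fatty acid use exceeded the TMM shift of 0.20 in type IIb-like nuclei. The KIC share with Myog was 3.10% and rho 0.196 in type IIb-like nuclei. Without the KIC clusters that have no subtype Myh1 was 0.64, sarcomere 0.0146 and fatty acid use 0.000311, and without the low-myosin clusters Myh1 was 0.19. Myh2 was 0.43 in FAPs with doublets kept and -0.0103 in myotendinous junction nuclei with the mean of each nucleus's CPM. In the latter class NF-kB was -0.0189 with members of at least 1 UMI, and with at least 100 UMIs immediate-early genes were -0.17 and 7 lists stood apart, as fewer members were measured. The body share was 62.9% in control and 76.4% in KIC with the stricter filter, 45.7% and 68.95% with doublets kept, and 63.9% in control at resolution 0.5. Thinning lowered the shares with Myog to 0.247% and 1.82%, since fewer UMIs remained. Peak overlap was 79.4% and 74.2% at a reciprocal 50% and 92.4% and 82.6% for peaks with at least 200 counts. At a reciprocal 90%, 13 named peaks had their direction, since fewer peaks are shared, and rho was 0.306. With 200 UMIs and 200 counts rho was 0.348, and with both gene ends summed 0.341.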

Other observations

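Id1, Id2 and Id3, inhibitors of helix-loop-helix factors, were highest in the KIC body myonuclear clusters that hold the most Ncam1, although the myostatin, activin and BMP list they belong to did not stand apart in body myonuclei. They stood at 45.0, 29.6 and 40.9 CPM in cluster 4 and at 68.0, 69.8 and 55.3 CPM in cluster 12, against 0.885, 0 and 1.77 CPM in KIC cluster 1 and 0.624, 0 and 0 CPM in control cluster 0. Stat3, the transcription factor that carries IL-6 signals, stood at 301 and 356 CPM in clusters 4 and 12, 199 CPM in cluster 1 and 86.1 CPM in control cluster 0. The clock repressor Cry2 and the autophagosome gene Map1lc3b were highest in cluster 1 among these clusters, at 397 and 151 CPM, with 70.1 and 54.0 CPM in cluster 4 and 22.5 and 18.1 CPM in control cluster 0. Accessibility at the gene ends of body myonuclei was higher for Id1 (1.64, 1.30 to 1.98) and Id3 (0.64, 0.42 to 0.86), and no difference was detectable for Id2 (0.23, -0.03 to 0.50) and Cry2 (0.10, -0.06 to 0.25). No test was run on these values, and the clusters were formed on the same counts.

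Fbxo32 and Trim63 RNA was also seen in classes too small to compare. In KIC the genes together stood at 56.8% of the body level in Schwann-like nuclei, 38.9% in satellite cells, 35.8% in lymphatic endothelial nuclei, 34.7% in macrophages, 22.8% in endothelial nuclei, 20.9% in adipocytes and 1.5% in tenocytes. In control they stood at 2.99%, 67.6%, 2.16%, 23.9%, 5.76%, 43.9% and 9.31%. Ttn, Neb, Trdn and Ryr1, taken as a rough measure of muscle RNA summed over each class, stood in KIC at 12.3%, 50.7%, 14.6%, 31.7%, 24.0%, 34.9% and 0.344% of the body level in the same order, and in control at 0.379%, 75.3%, 0.224%, 18.7%, 5.78%, 40.4% and 13.3%. In KIC endothelial nuclei, adipocytes and satellite cells that background was higher than the share of Fbxo32 and Trim63. The measure differs between myonuclei, however. KIC cluster 1 held 13064 CPM of Fbxo32 and 15073 CPM of Trim63 with 15126 CPM of Ttn, against 6265, 5615 and 34615 CPM in KIC cluster 3. The higher shares in KIC Schwann-like and lymphatic endothelial nuclei therefore cannot be told apart from RNA carried over from such myonuclei.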
